A study of Mus musculus with 8 samples.

How the data were processed

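RNA was measured in whole kidney of 8 male mice, 20 weeks old, on the C57BLKS/J background. There were 4 groups of 2 mice each, so every group has n = 2. Normal mice carried a working leptin receptor. The db/db mice carried the Leprdb mutation on both chromosomes, which inactivates the long form of the leptin receptor, and such mice become obese and diabetic. A group of db/db mice was left untreated, a group received nanoparticles (labelled PEI) with a control miRNA, and a group received the same kind of nanoparticles with a mimic of miR-181b-5p. A mimic is a synthetic double-stranded RNA that acts as the mature miRNA and lowers mRNAs that pair with its seed. Dose, route and schedule of the treatment are not given in the sources used here.

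The arrays were Agilent mouse gene expression arrays with 60-base probes, hybridised with 1 dye. Per the labels, RNA was isolated on RNeasy columns, and Cy3-labelled cRNA was made from 50 ng of total RNA with the Low Input Quick Amp kit. The scanner output of Agilent Feature Extraction 12.0.3.1 holds, per the file headers, the intensity of each spot, its local background and its quality calls. The deposited series table holds a ratio for 56745 probes: each value equals the probe's intensity after the authors' scaling of every array to its 75th percentile, divided by the probe's median over the 8 arrays. This scale was found from the values. The table correlated with rescaled scanner values at r from 0.9995 to 0.9999 over the 8 columns, and 100% of probes had a median log2 ratio of 0. The ratio is linear, is centred per probe and not per array, and rises with expression. Its column medians were 1.05 and 1.08 for the normal mice, 0.979 and 0.992 for untreated db/db mice, 0.995 and 0.971 after control miRNA, and 0.977 and 1.03 after the mimic. All value columns were matched to a sample.

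Processing started from the scanner intensity after the background subtraction and detrending of Feature Extraction, which replaces spots at background by small positive values. Each of the 8 arrays held 59305 spots of 56605 non-control probes. Spots of 1 probe were averaged, and 4 probes were dropped for outlier calls. Intensities were divided by the 75th percentile of the array and put on the log2 scale, so a level of 0 is the 75th percentile of that array. Probes had to lie well above background on both arrays of at least 1 group, which kept 33640 probes. Names followed the RefSeq gene table of the mouse GRCm38.p6 assembly: 33762 probes were named by transcript accession, 9871 by symbol and 310 by synonym, while 12662 kept the name in the array annotation. Coordinates are probe positions of the array annotation on the mm9 build. A gene with several probes, the case for 7634 genes, was represented by the probe with the highest mean level over all 8 arrays. This left 22379 genes, of which 19271 lay well above background on all 8 arrays.

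Between 56.5% and 62.5% of spots per array lay well above background, the median signal was 35.7 to 46.7 units and the 75th percentile 489 to 651 units, and 0 spots were saturated. Each comparison sets 2 arrays against 2. All 8 arrays sat on 1 slide and were scanned in 1 run. The normal and untreated db/db mice lay in array row 1 and the mice given nanoparticles in array row 2. The row is therefore confounded with the nanoparticles wherever a treated group is set against untreated mice. The normal and control miRNA mice lay in array columns 1 and 2, and the untreated db/db and mimic mice in columns 3 and 4. The column is therefore confounded with the group in every comparison except that of mimic with untreated mice, so no comparison is free of the array's place on the slide.

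A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (4 residual and 2.23 prior degrees of freedom), and p-values were adjusted over the 22379 genes by the Benjamini-Hochberg method. A gene passed at an adjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so every p rests on the shared variance of the model, and the groups of 2 leave too few other splits of the arrays to count. Errors printed after ± are standard deviations over the 2 mice of a group. A fold is written as at least N-fold when the gene lay well above background on none of the arrays of 1 group, because the fitted ratio is then not a measurement. The bound compares the mean of the other group with the dim group's values after these are raised to the lowest signal that counted as well above background on each array.

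Expression of 40 gene lists was tested with limma's camera (inter-gene correlation 0.01) and adjusted over the lists. The lists held markers of kidney and other cell types, metabolic and stress pathways, androgen-dependent and female-biased kidney genes, clock and glucocorticoid-response genes, and reported miR-181 targets. Each list was run again with a correlation estimated from the arrays and with fry, which uses the correlation of the members and tests a list against no change, whereas camera tests it against the other genes. Members were also adjusted over their own list alone. The camera test takes little account of correlated members, and the other methods are the stricter reading. Ranges of a list's adjusted p over the settings are from camera at the fixed correlation and leave out the estimated correlation and fry. Markers of fat, renal pelvis and liver, separate from the lists, served in the closing tests.

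Genes are named by a rule. Among genes with a standard symbol that passed, whose groups did not overlap and that lay well above background on at least 1 array of each group, the 10 largest rises and the 10 largest falls are given, with the 3 largest bounds in each direction. A set of kidney disease and miR-181 genes is reported whether or not they passed, and each list that passed is shown by members with the smallest p. In comparisons in which no gene passed, the 5 genes with the smallest p in each direction are given. Some genes that this rule picks are not reported here. Groups, comparisons, the threshold, the lists and most alternative settings were chosen before the data were examined. The alternatives were normexp background correction (offset 50), quantile normalization, the deposited ratios, no filter and a filter on all 8 arrays, a model on the compared groups alone, the replicate number as a block, a trended robust prior, array weights, other ways of joining probes, and leaving out each array in turn. Settings added after seeing the data were the fits without mimic replicate 1, with or without normal replicate 1, in comparisons where those arrays are not the treated group, and the fits without probes that hold CA or GT repeats.

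The model was tested on simulated data with the spread of these arrays, in which 200 of 22379 genes were changed. For db/db against normal mice, 2% of genes changed 1.5-fold, 36% changed 2-fold, 58% changed 4-fold and 84% changed 8-fold were recovered, and 3 of 93 calls were false. For mimic against control miRNA these shares were 4%, 38%, 66% and 90%, with 7 false calls of 106. For control miRNA against untreated mice they were 0%, 48%, 74% and 84% (10 of 113), and for mimic against untreated mice 0%, 44%, 70% and 82% (2 of 100). All 4 simulations used the same spread of each gene, pooled over the groups, so their shares differ only by the random draw. In the real arrays the spread was widest between the mimic mice. These shares therefore do not give the recovery or the false calls of each real comparison. A test of a shift of mRNAs by miR-181 seed sites in their 3′ untranslated regions was not run, because those sequences were not used here; sites inside the probe sequences were tested instead. Computation outside limma used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.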

Results

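The study asked what a miR-181b-5p mimic carried by nanoparticles changes in the kidney of the diabetic db/db mouse. Expression was read on 8 kidney arrays from 4 groups of 2 mice each: normal, untreated db/db, db/db given a control miRNA and db/db given the mimic. Replicate arrays correlated at r from 0.992 to 0.997 in the first 3 groups, and at r = 0.976 for the mimic. Between replicates, 685 genes lay more than 2-fold apart in normal kidney, 164 in untreated db/db kidney, 358 after control miRNA and 2471 after the mimic. Mimic replicate 1 stood apart from all other arrays on the first principal component, which held 45.1% of the variance (81.4 against 17.7 for mimic replicate 2).

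The comparison of untreated db/db with normal kidney gives the effect of the diabetic genotype, although array column and genotype cannot be separated. Lepr, the leptin receptor gene that carries the db mutation, had a log2 level of 2.295 ± 0.011 in db/db and 3.097 ± 0.028 in normal kidney (n = 2 each; chromosome 4, 101452666 to 101452725 on mm9). This change of -0.80 did not pass over all genes in limma (Benjamini-Hochberg adjusted p = 0.0550). A second Lepr probe, A_55_P2506350 on chromosome 4 at 101486122 to 101486181, fell by 2.16 on the log2 scale, or 4.47-fold (adjusted p = 0.0482 over probes).

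Cyp4a14, Gsta2 and Gc had the largest rises in db/db kidney. Cyp4a14 (chromosome 4), a fatty acid hydroxylase, rose 26.2-fold from -4.27 ± 0.94 to 0.45 ± 0.08 (n = 2 each, adjusted p = 0.0172 in limma). Its level on normal replicate 2 (-4.93) lay below the lowest signal well above background on that array (-4.87), so the size of this fold is uncertain. Fabp1 (chromosome 6), a fatty acid carrier, rose 8.63-fold (0.0322). Gc (chromosome 5), the vitamin D-binding protein of plasma, rose 17.6-fold from 1.27 ± 0.32 to 5.40 ± 0.05 (0.0172). Cyp27b1 (chromosome 10), which makes active vitamin D, rose 8.65-fold from -2.14 ± 0.35 to 0.97 ± 0.01 (0.0231), and Cyp24a1 (chromosome 2), which breaks it down, rose 10.3-fold from 1.12 ± 0.11 to 4.48 ± 0.36 (0.0308). Gsta2 (chromosome 9), a glutathione transferase, rose 25.1-fold from 0.67 ± 0.44 to 5.31 ± 0.07 (0.0271). Kynu (chromosome 2), an enzyme of tryptophan breakdown, rose 13.7-fold (0.0310), Bhmt (chromosome 13), a homocysteine methyltransferase, 8.67-fold (0.0271), and Asb11 (chromosome X) 7.58-fold (0.00876). F10, which encodes coagulation factor X, rose at least 5.30-fold (0.0338), Crabp1, a retinoic acid carrier, at least 5.13-fold (0.0443) and Rasl10b at least 1.66-fold (0.0162).

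The largest falls in db/db kidney included transporters of organic anions. Slco1a1 (chromosome 6, 141856493 to 141856552) fell 115-fold from 2.58 ± 0.61 to -4.26 ± 0.30 (n = 2 each, adjusted p = 0.00340 in limma), and Slc22a7 (chromosome 17, 46569272 to 46569331) fell 102-fold from 5.67 ± 0.22 to -1.01 ± 0.19 (0.0109). Slc22a26 (chromosome 19) fell 22.9-fold (0.00633). Cyp7b1 (chromosome 3), an oxysterol hydroxylase, fell 21.1-fold from 5.65 ± 0.13 to 1.25 ± 0.20 (7.68e-04), and Acsm3 (chromosome 7), a medium-chain fatty acid-CoA ligase, fell 16.9-fold from 5.65 ± 0.42 to 1.57 ± 0.06 (0.0162). Alox15, a lipoxygenase on chromosome 11, fell 29.7-fold (0.00817), and Masp2, a protease of the lectin pathway of complement on chromosome 4, fell 24.1-fold (0.00517). Albfm1 fell 20.9-fold (0.0271), Ceacam13 18.9-fold (0.0271) and Ldc1 13.5-fold (0.0299). Sec14l3 (chromosome 11, 3978896 to 3978955) fell at least 79.4-fold and had the smallest adjusted p of all genes (3.25e-05). Ctxn3 fell at least 7.03-fold (0.0171) and the long noncoding RNA Sox2ot at least 6.09-fold (1.40e-04).

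**Figure D1:**
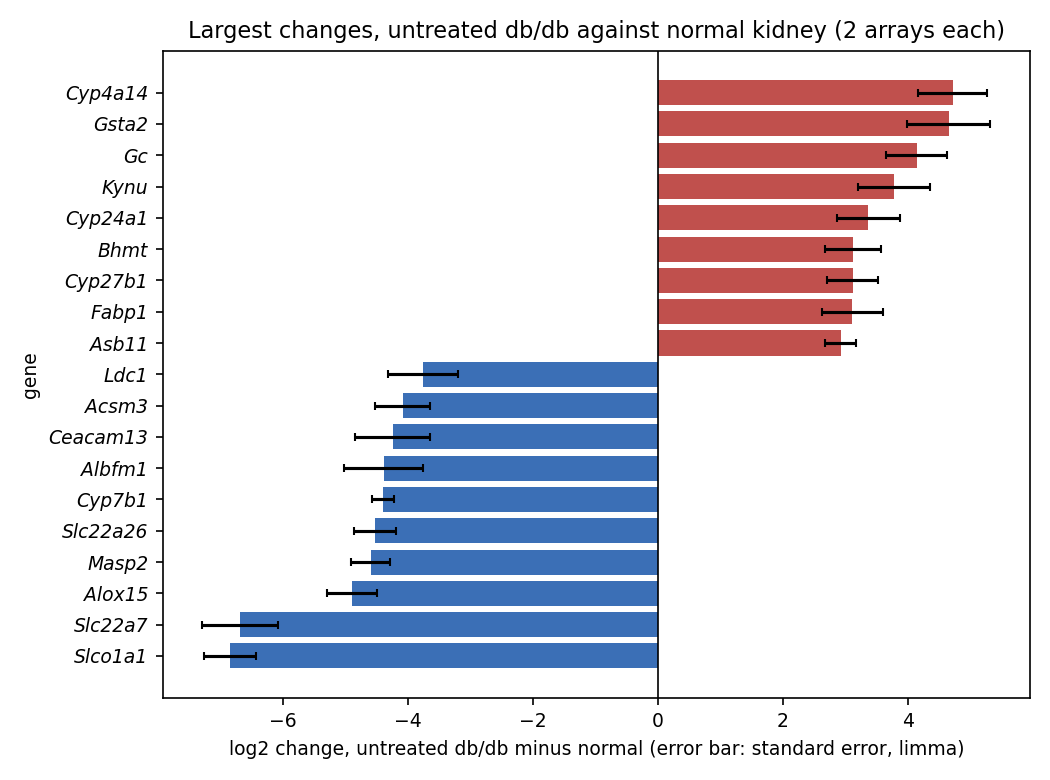
Bars give the log2 change of 9 of the largest rises (red) and of the 10 largest falls (blue) that passed, untreated db/db minus normal kidney, 2 mice per group, with the standard error of the limma model as error bars. Changes ran from -6.84 for Slco1a1 to 4.71 for Cyp4a14.

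In all, 784 of 22379 genes differed between db/db and normal kidney, 278 higher and 506 lower, with a median log2 change of 1.18 and -1.17. Of these, 519 differed at least 2-fold, 182 higher and 337 lower, and at an unadjusted p under 0.05 there were 5524 genes, 24.7% of those tested. The 2 groups did not overlap for 63.3% of genes, against 33.3% by chance. Under quantile normalization the split was 475 higher and 478 lower. The count depended on single arrays: it was 20 without untreated replicate 1, 28 without untreated replicate 2, 55 without normal replicate 1 and 54 without normal replicate 2, and it was 3342 without mimic replicate 1, whose spread enters the shared variance. All 26 of the genes that the naming rule picked for their size of change kept their direction in these fits, but between 5 and 7 of them passed when an array of a compared group was left out.

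Androgen-dependent kidney genes were lower and proliferation genes higher as lists in db/db kidney in camera, though not with an estimated correlation (adjusted p = 0.477 and 0.590). Of 14 measured androgen-dependent genes, 6 fell, 10 fell when adjusted over the list alone, and the others did not pass; the median was -1.42 (camera adjusted p = 2.53e-08, adjusted p = 0.477 with an estimated correlation, fry adjusted p = 0.00937). Examples besides Slco1a1 and Cyp7b1 were Cyp4b1 (-1.95, adjusted p = 0.0172), Ugt2b38 (-1.72, 0.0264) and Cyp2e1 (-1.40, 0.0418). Female-biased kidney genes were higher as a list of 10 (median 1.35, 0.00706, adjusted p = 0.590 with an estimated correlation). Cyp4a14 alone passed over all genes, while 7 rose and 2 fell over the list alone, and Cyp2a4 stood at -1.59 (0.0511) and Abcc3 at 1.38 (0.0808). Of 26 proliferation genes, 1 passed over all genes and 19 over the list alone, all higher, with a median of 1.23 (2.42e-10, adjusted p = 0.590 with an estimated correlation). Top2a, which relaxes DNA in dividing cells, rose by 1.89 (0.0171), and Ccne1 (1.04, 0.0508), Birc5 (1.62, 0.0516) and Mcm5 (1.28, 0.0558) did not pass. Calls of single members were fragile: of 25 members of these and the other lists that passed in this comparison, 2 passed without untreated replicate 1, 2 without untreated replicate 2, 5 without normal replicate 1 and 4 without normal replicate 2. The female-biased list missed the threshold among genes well above background on all 8 arrays (range over the settings 3.10e-04 to 0.0552).

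Markers of the glomerulus and of the distal tubule were higher as lists in db/db kidney in camera, though not with an estimated correlation. Of 16 podocyte genes, 4 rose over all genes and 8 over the list alone (median 0.62, camera adjusted p = 5.70e-07, adjusted p = 0.477 with an estimated correlation, fry adjusted p = 0.0242). They included Wt1, the podocyte transcription factor (1.24, adjusted p = 0.0155), Synpo (1.26, 0.0224), Podxl (1.34, 0.0260) and Cdkn1c (1.71, 0.0448), while the slit diaphragm gene Nphs1 (1.06, 0.0611) did not pass. A second probe for Wt1 went the other way (-0.73), as did 1 of 4 probes for Synpo (-0.06). Of 16 endothelial genes 3 rose by either count (median 0.26, 7.12e-04, adjusted p = 0.590 with an estimated correlation, fry 0.0347), namely the angiopoietin receptor Tek (1.10, 0.0160), Ehd3 (1.04, 0.0162) and Eng (0.71, 0.0363). Of 11 distal convoluted tubule genes 1 rose, and 4 rose over the list alone (median 0.59, 9.38e-04, adjusted p = 0.601 with an estimated correlation). Trpv5, the apical calcium channel, rose by 1.49 (0.0377), and Calb1, the calcium carrier calbindin, stood at 1.99 (0.0650). These differences went with fewer urothelial transcripts in db/db kidney, whose median was -2.82.

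Markers of urothelium, which lines the renal pelvis, and of fat were lower as lists in db/db kidney. Of 11 urothelial genes 0 passed over all genes and 7 fell over the list alone (median -2.82, camera adjusted p = 9.38e-04, adjusted p = 0.601 with an estimated correlation). Upk1b (-4.12, adjusted p = 0.0955), Upk2 (-3.59, 0.0972) and Psca (-2.94, 0.0914) did not pass. Of 12 adipocyte genes 0 passed and 1 fell over the list alone, Cfd (-8.61, 0.0647; median of the list -0.74, 0.0204, adjusted p = 0.590 with an estimated correlation). The level of Cfd in normal kidney was 3.17 ± 2.93 and that of Cidea 0.30 ± 3.61. The 2 normal arrays differed by a median of 1.97 for adipocyte and 1.86 for urothelial genes. Without normal replicate 1 the adipocyte call ended (median -0.45, adjusted p = 0.184, range over the settings 5.38e-04 to 0.303).

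Immune cell genes were lower as lists in db/db kidney. Of 19 macrophage genes 2 fell by either count (median -0.81, camera adjusted p = 4.58e-04, adjusted p = 0.699 with an estimated correlation), Ms4a7 (-1.78, adjusted p = 0.0112) and Csf1r, the receptor for the macrophage growth factor (-1.26, 0.0276), while Aif1 stood at -1.77 (0.118). Of 16 T and NK cell genes 0 passed over all genes and 14 fell over the list alone (median -0.96, 2.13e-06, adjusted p = 0.590 with an estimated correlation), with Cd3d at -1.03 (0.0511) and Cd5 at -0.88 (0.0559). Interferon-response genes, of which 0 of 27 passed by either count, had a median of -0.84 (0.0144, adjusted p = 0.850 with an estimated correlation), with Oas2 at -2.31 (0.0898) and Ifi44 at -0.86 (0.0731). The interferon call ended without normal replicate 1 (-0.79, adjusted p = 0.0719) and under normexp (-0.58, 0.0787; range over the settings 2.49e-07 to 0.0787). Red cell genes were higher as a list of 7 (median 3.74, 0.00266, adjusted p = 0.590 with an estimated correlation), with 0 passing by either count. Hbb-b1 stood at 4.03 (0.218) and Alas2, the heme enzyme of red cells, at 3.52 (0.209). The level of Hbb-b1 was -3.48 and -2.10 in normal kidney, 1.04 and 1.45 in db/db kidney, and 1.90 and -4.01 on the mimic arrays. Interferon-response genes differed by a median of 1.70 between the mimic arrays and 0.05 between the untreated arrays. The mimic spread enters the shared variance, so these gene p values do not measure the spread within the compared groups alone.

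Glucocorticoid-response and clock genes were higher as lists in db/db kidney in camera, though not with an estimated correlation. Of 16 glucocorticoid-response genes 3 rose over all genes and 6 over the list alone (median 0.65, camera adjusted p = 3.24e-04, adjusted p = 0.590 with an estimated correlation): Per1 (1.76, adjusted p = 0.00524), the metallothionein Mt1 (0.70, 0.0397) and Sult1a1 (1.12, 0.0470). Sgk1, a kinase that raises sodium uptake, stood at 2.03 (0.0765). Of 20 clock genes 3 rose and 1 fell over all genes, and 4 rose and 1 fell over the list alone (median 0.78, 0.00223, adjusted p = 0.590 with an estimated correlation). Per1, Per2 (2.44, 0.0493) and Wee1 (1.81, 0.0215) rose, while Npas2, a partner of the clock activator Arntl, fell at least 2.75-fold (0.0482).

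Lists of metabolism and of the translation machinery moved by small medians. Fatty acid oxidation genes (35 measured) had 3 rises and 1 fall over all genes, 6 and 2 over the list alone, and a median of 0.19 (camera adjusted p = 0.00979, adjusted p = 0.792 with an estimated correlation); Cyp4a14 and Fabp1 were among those that rose, and the fatty acid transporter Cd36 fell by 3.14 on the log2 scale (adjusted p = 0.0444). Respiratory chain genes (40) had a median of 0.19 (7.12e-04, adjusted p = 0.850 with an estimated correlation) and ribosomal protein genes (36) a median of 0.09 (0.00195, adjusted p = 0.850 with an estimated correlation), with 0 members passing by either count. Rps2 stood at 0.62 (0.0570) and Atp5g1 at 0.33 (0.159). Quantile normalization ended all 3 of these calls (0.293 for fatty acid oxidation, 0.451 for the respiratory chain and 0.855 for ribosomal proteins), and leaving out normal replicate 1 ended those of fatty acid oxidation (median -0.02, 0.198) and of the respiratory chain (0.05, 0.129). The adjusted p ranged from 9.30e-05 to 0.337, from 7.89e-07 to 0.451 and from 1.13e-05 to 0.855 over the settings of these 3 lists.

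The other 23 lists did not pass in this comparison. Their medians were 0.09 for proximal tubule, 0.10 for mesangium and fibroblasts, 0.11 for the thick ascending limb, 0.02 for collecting duct, 0.13 for intercalated cells, -0.46 for B and plasma cells, 0.06 for neutrophils, -0.03 for adrenal tissue, -0.18 for tubular injury and 0.16 for extracellular matrix. They were -0.01 for inflammatory cytokines, -1.14 for antigen presentation, -0.33 for complement, 0.13 for senescence and p53, 0.01 for apoptosis, 0.13 for glucose production, -0.09 for lipid synthesis and -0.20 for oxidative stress. They were 0.34 for renin and angiotensin, -0.02 for ER stress, 0.09 for immediate early genes, -0.37 for heat shock and 0.08 for reported miR-181 targets. Means opposite in sign to the medians were -0.06 for proximal tubule, -0.02 for collecting duct, 0.20 for adrenal tissue, 0.05 for oxidative stress and 0.01 for ER stress, and camera pointed down for neutrophils. Of the kidney disease genes, Col1a1 (-1.23, adjusted p = 0.282), Timp3 (-0.59, 0.0660), Kpna4 (-0.42, 0.0907), Fn1 (0.37, 0.659), Cdkn1a (0.91, 0.523), Bcl2 (0.22, 0.409), Lcn2 (-0.12, 0.976), Col4a1 (0.01, 0.993) and Tgfb1 (-0.01, 0.983) did not pass.

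The comparison of mimic with control miRNA gives the effect of miR-181b-5p itself, since both groups received nanoparticles, although array column and mimic cannot be separated. No gene passed in limma (0 of 22379; smallest adjusted p = 0.140), and 2082 genes, 9.30%, had an unadjusted p under 0.05, where 5% is expected by chance. The 2 groups did not overlap for 39.4% of genes, against 33.3% by chance. The count stayed at 0 under every other setting that kept both mimic arrays. Among the genes with the smallest p that were higher after the mimic were Mt2, a metallothionein (6.75 ± 0.17 against 5.69 ± 0.01, n = 2 each, difference 1.05), Bdkrb2, a bradykinin receptor (1.14), Pramel25 (1.08) and Ccdc138 (1.36), all with an adjusted p of 0.140. A second probe for Ccdc138 went the other way (-0.73). Those that were lower were Alox5, a lipoxygenase of leukotriene synthesis (-4.35 ± 0.10 against -2.78 ± 0.07, difference -1.56), and 4 genes below reliable detection after the mimic: Rhox4a (at least 1.78-fold), Tmem269 (at least 1.52-fold), Tceanc2 and Gli3 (each at least 1.19-fold).

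Genes reported as miR-181 targets did not move as a group after the mimic. Of 28 measured, 0 passed by either count, the median was -0.02 and the camera adjusted p was 0.425. Timp3 stood at -0.32 (adjusted p = 0.547), Bcl2 at -0.18 (0.693), Atm at -0.27 (0.547) and Kpna4, which imports NF-kB into the nucleus, at -0.01 (0.988). The kidney disease genes Nphs1 (-0.06), Col1a1 (-0.00), Col4a1 (0.24), Fn1 (0.16) and Tgfb1 (0.08) did not pass either, nor did Lepr (-0.07). Lcn2 (2.75, 0.633) and Cdkn1a (1.92, 0.537) differed widely between the mimic mice, at 1.80 ± 4.40 and 0.82 ± 1.80.

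Lists moved by mimic replicate 1 alone included those of immunity, injury and stress. On that array the antigen presentation list lay 3.48 above control, the neutrophil list 2.39, interferon response 1.60, macrophage 1.58, complement 1.33, inflammatory cytokines 1.21, tubular injury 1.19, immediate early genes 0.93 and ER stress 0.54. On mimic replicate 2 the same medians were 0.04, -0.31, -0.04, -0.13, 0.04, -0.02, -0.08, 0.08 and 0.01. Markers of 4 tubule lists lay lower on mimic replicate 1 and not on mimic replicate 2, with medians of -1.01 and 0.09 for the thick ascending limb, -0.59 and 0.00 for proximal tubule, -0.53 and 0.13 for collecting duct and -0.51 and 0.26 for the distal convoluted tubule, though none of these 4 lists passed. Intercalated cell markers were not lower than in untreated db/db kidney, with medians of 0.14 on mimic replicate 1 and 0.24 on mimic replicate 2. With both arrays the 9 lists of immunity, injury and stress passed in camera, with adjusted p from 2.47e-07 for interferon response to 0.0342 for neutrophils, but their adjusted p lay between 0.715 and 0.740 with an estimated correlation. Without mimic replicate 1 none of the 9 stayed higher, and the macrophage list was lower (-0.13, adjusted p = 0.0151, range over the settings 1.33e-09 to 0.157). With both arrays 0 members of the 9 lists passed, over all genes or over their list alone, except 2 macrophage genes that were lower over the list alone, Itgam (-1.79, 0.157) and Ms4a7 (-0.79, 0.216). Tap1, which loads peptides for antigen presentation, stood at 2.33 (0.606), Cxcl10 at 1.49 (0.601), S100a8 at 2.61 (0.634) and Clu, a gene of injured tubules, at 0.94 (0.469). Podocyte genes (0.16, 0.0414), ribosomal protein genes (0.12, 8.51e-05) and oxidative stress genes (0.06, 0.0175) also passed in camera, with adjusted p of 0.715, 0.740 and 0.715 with an estimated correlation. The podocyte and ribosomal calls ended without mimic replicate 1 (0.10, adjusted p = 0.234, and -0.00, 0.817), and the oxidative stress call ended without mimic replicate 2 (0.03, 0.0864) or control replicate 1 (0.10, 0.0625). The neutrophil call also ended without control replicate 1 (1.13, 0.103), the macrophage call without control replicate 2 (0.56, 0.157) and the podocyte call without control replicate 2 (0.10, 0.260). Over the settings the adjusted p ranged from 0.0141 to 0.260 for podocyte, 3.30e-06 to 0.928 for ribosomal protein, 0.00531 to 0.173 for oxidative stress and 2.76e-07 to 0.114 for neutrophil genes.

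On both mimic arrays, glucocorticoid-response, fatty acid oxidation and heat shock genes lay higher, and lipid synthesis and androgen-dependent genes lower, than after control miRNA. The 16 glucocorticoid-response genes had medians of 1.15 and 0.67 on the 2 arrays (camera adjusted p = 8.43e-09), with 0 passing over all genes and 8 higher over the list alone. They included Mt2 (1.05), Mt1 (0.67, adjusted p = 0.157), Tsc22d3, the leucine zipper GILZ (1.17, 0.161), and Per1 (0.52, 0.268), and a second probe for Mt1 stood at -0.02. The 35 fatty acid oxidation genes had medians of 0.49 and 0.23 (8.75e-07; 4 higher over the list alone), with Creb3l3 at 2.44 (0.140) and Pex11a at 0.80 (0.176). The 17 heat shock genes had medians of 0.66 and 0.27 (8.75e-07; 0 over the list alone), with the chaperones Hsph1 at 0.80 (0.403) and Chordc1 at 0.64 (0.359). The 31 lipid synthesis genes had medians of -0.33 and -0.14 (0.00208; 0 over the list alone), with Idi1 of the mevalonate pathway at -0.90 (0.278) and Insig1 at -1.14 (0.302). The 14 androgen-dependent genes had medians of -1.02 and -0.22 (0.0115; 2 lower over the list alone), with Slco1a1 at -2.70 (0.140; at least 2.51-fold) and Cyp7b1 at -0.98 (0.157). Each of these 5 calls stayed when either mimic array was left out, but all had an adjusted p of 0.715 with an estimated correlation, and fry gave adjusted p of 0.370 or more.

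The other lists did not pass in this comparison, including the clock genes (20 measured; median -0.01, camera pointing up, 4 higher and 1 lower over the list alone) and red cell genes (median -1.73; 1.08 and -4.54 on the 2 arrays). Adipocyte genes had a median of -0.26 with camera pointing up, urothelial genes a median of -0.49 and extracellular matrix genes -0.03. T and NK cell genes stood at -0.25, in contrast to the macrophage and neutrophil lists. When mimic replicate 1 was left out, 112 genes passed (75 higher, 37 lower), and 3084 passed without mimic replicate 2. Of the 112 genes, 90 were read by probes that hold a CA or GT repeat of at least 6 units, 19 with CA and 71 with GT, though such probes read 154 of the 22379 genes. The 47 genes with a CA repeat probe had a median of -1.53 and the 107 with a GT repeat probe a median of 1.81 after the mimic, and both mimic arrays showed it (-2.04 and -1.04 for CA, 2.26 and 1.38 for GT). In the comparison of db/db with normal kidney these medians were -1.15 and 0.94, and 1 of the 784 genes had such a probe. Itgam, Junb and Ccdc138 were read by repeat probes.

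**Figure D2:**
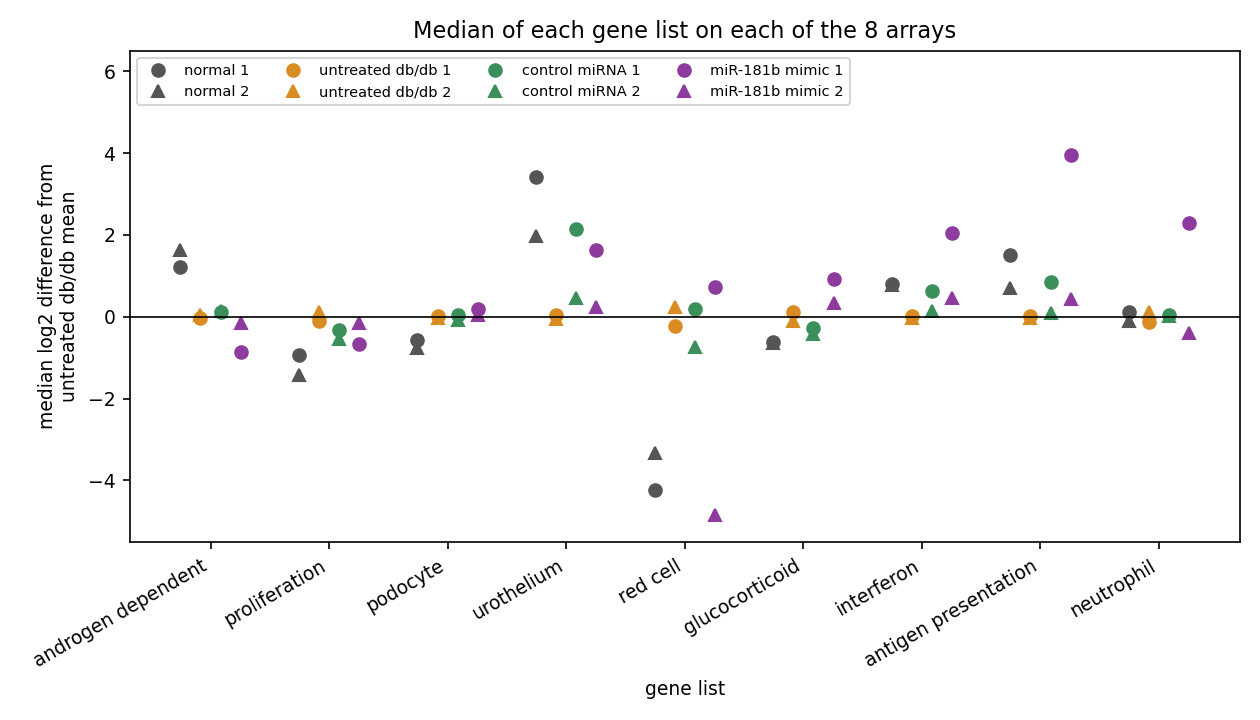
Each point is the median log2 difference of a gene list on 1 array from the mean of the untreated db/db arrays, for 9 lists and 8 arrays (circle, replicate 1; triangle, replicate 2; color, group). Mimic replicate 1 lay 3.96 above untreated db/db for antigen presentation and mimic replicate 2 lay 0.44 above.

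**Figure D3:**
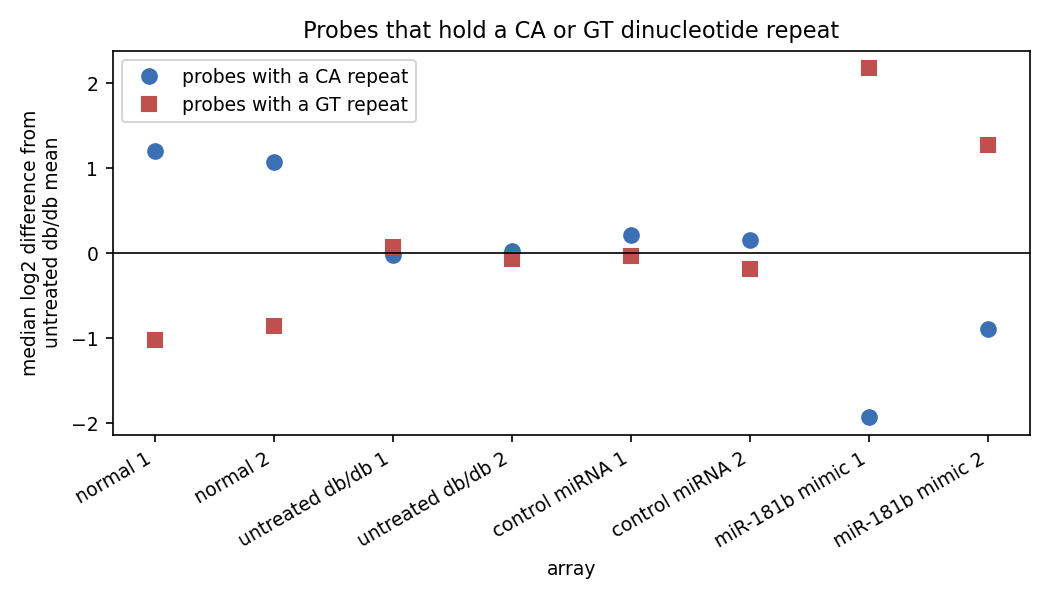
Each point is the median log2 difference from the mean of the untreated db/db arrays, on 1 array, over genes read by a probe with a CA repeat (circles, 47 genes) or a GT repeat (squares, 107 genes). The mimic arrays lay at -1.93 and -0.89 for CA and at 2.18 and 1.28 for GT.

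The comparison of control miRNA with untreated db/db kidney gives the effect of nanoparticles with a control RNA, and here array row, array column and treatment cannot be separated. No gene passed in limma (0 of 22379; smallest adjusted p = 0.913, Smim40, at least 1.62-fold lower), and 725 genes, 3.24%, had an unadjusted p under 0.05, below the 5% expected by chance. The 2 groups did not overlap for 39.8% of genes, against 33.3% by chance, and the count was 0 under all settings. After Smim40, the smallest p values belonged to Cdr2 (-0.77), Cyp4a29 (at least 1.19-fold lower), Negr1 (at least 2.03-fold lower) and Adgrf3 (at least 1.41-fold lower), and to Cd84 (at least 1.57-fold higher), Rims2 (at least 1.72-fold higher), Zfp607b (0.73), Snx29 (0.77) and Pwwp2a (0.52), each with an adjusted p that rounds to 1. Proliferation genes were lower as a list of 26 (median -0.48, camera adjusted p = 5.71e-07), with Top2a at -0.75 and Birc5 at -0.83. Glucocorticoid-response genes (16, median -0.30, 0.00497), with Zbtb16 at -1.89 and Per1 at -0.50, and endothelial genes (16, median -0.13, 0.0269), with Ehd3 at -0.21, were also lower as lists. Urothelial genes (11, medians 2.15 and 0.46 on the 2 arrays, 0.00139), interferon-response genes (27, 0.63 and 0.15, 0.00401) and macrophage genes (19, 0.49 and 0.14, 0.0157) were higher as lists, with Upk1b at 2.62, Oas2 at 1.00 and Ms4a7 at 0.78. All 6 lists had an adjusted p of 0.983 with an estimated correlation and 0.995 in fry, and 0 members passed by either count. Without control replicate 1 the urothelial (0.46, adjusted p = 0.268), interferon (0.15, 0.388), macrophage (0.14, 0.347) and endothelial (-0.11, 0.135) calls ended, and without untreated replicate 1 the glucocorticoid (-0.19, 0.203), macrophage (0.26, 0.136) and endothelial (-0.12, 0.0703) calls ended. The endothelial call also ended without untreated replicate 2 (-0.12, 0.142), and 12 lists passed without control replicate 2. Over the settings the adjusted p ranged from 8.72e-09 to 0.268 for urothelial, 2.65e-10 to 0.388 for interferon-response, 3.71e-07 to 0.347 for macrophage, 0.00477 to 0.142 for endothelial and 1.71e-04 to 0.203 for glucocorticoid-response genes, while proliferation genes passed under all of them (3.66e-09 to 5.40e-05).

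The comparison of mimic with untreated db/db kidney joins the effects of nanoparticle, array row and mimic. No gene passed in limma (0 of 22379; smallest adjusted p = 0.0742), 3104 genes, 13.9%, had an unadjusted p under 0.05, and the 2 groups did not overlap for 47.8% of genes, against 33.3% by chance. Alox5 (-1.88, adjusted p = 0.0742), Tmem269 (at least 2.33-fold lower, 0.0742) and the predicted gene Gm3230 (-2.41, 0.0742; chosen after its value was seen) came nearest, followed by Mt2 (1.38, 0.114), Pip5k1a (1.26, 0.114; other probes down to -0.35), Gli3 (at least 1.49-fold lower, 0.114), Tceanc2 (at least 1.21-fold lower, 0.114), Armc2 (at least 1.05-fold lower, 0.114), Rbm14 (0.97, 0.119), Pramel25 (1.07, 0.119) and Snora23 (at least 2.18-fold higher, 0.119). Without mimic replicate 2 the count was 4151, and it was 0 without mimic replicate 1 or either untreated replicate. In camera 19 lists passed, 16 higher and 3 lower, all with adjusted p of 0.636 to 0.705 with an estimated correlation and of 0.479 or more in fry. Lipid synthesis genes (31, median -0.33, 1.69e-04; 7 lower over the list alone) included Msmo1 (-1.11, 0.129) and Idi1 (-1.15, 0.141), while proliferation (26, -0.48, 3.92e-04) and androgen-dependent genes (14, -0.58, 0.0496; 2 lower over the list alone) were also lower. Interferon-response (27, 1.27, 5.47e-10), antigen presentation (16, 2.26, 1.33e-06), fatty acid oxidation (35, 0.37, 1.11e-05; 1 over the list alone) and heat shock genes (17, 0.47, 1.11e-05; 2 over the list alone) were higher on both mimic arrays, as were urothelial (11, 1.06, 0.0280) and intercalated cell genes (12, 0.17, 0.0469). The others that were higher were immediate early (0.56), complement (1.03), macrophage (1.06), ER stress (0.34), inflammatory cytokine (0.63), tubular injury (0.48), glucocorticoid-response (0.70; 3 higher and 2 lower over the list alone), ribosomal protein (0.13), neutrophil (1.10) and senescence genes (0.24).

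Without mimic replicate 1, 8 lists passed against untreated mice, 5 of them higher. The calls that ended were those of the immediate early (0.04, adjusted p = 0.281), complement (0.18, 0.510), macrophage (0.15, 0.591), ER stress (0.04, 0.325), inflammatory cytokine (0.03, 0.986), tubular injury (-0.03, 0.992), glucocorticoid-response (0.35, 0.284), ribosomal protein (0.01, 0.901), neutrophil (-0.40, 0.284), senescence (-0.03, 0.986), urothelial (0.23, 0.474), proliferation (-0.15, 0.191) and androgen-dependent lists (-0.15, 0.137). The intercalated call ended without mimic replicate 2 (0.14, 0.269) or untreated replicate 1 (0.19, 0.0880), the urothelial call without untreated replicate 1 (1.09, 0.0525), and without untreated replicate 2 the senescence (0.16, 0.152) and androgen-dependent calls (-0.57, 0.0989) ended. For each of these lists the largest camera adjusted p over the settings, leaving out the estimated correlation and fry, is among the values just given. The smallest ranged from 2.28e-10 for macrophage genes to 0.0156 for androgen-dependent genes.

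The question whether the mimic moves the diabetic kidney towards normal was put to the 784 genes that differed between db/db and normal kidney. Of these, 41.2% changed in the opposite direction after the mimic, relative to control miRNA, against 49.7% of all genes. Both comparisons set array columns 3 and 4 against columns 1 and 2. An effect of column would lower this share, so the share cannot be assigned to the mimic. Control miRNA against untreated mice sets columns 1 and 2 against columns 3 and 4, where a column effect would raise it. The share was 51.4% among genes that were higher in db/db kidney and 35.6% among those that were lower, and it was 44.3% on mimic replicate 1 and 37.5% on mimic replicate 2. Under normexp the share was 51.3%. The opposite-sign share was 76.9% for control miRNA and 59.7% for the mimic relative to untreated mice. Both of these comparisons share the untreated arrays with the db/db comparison, and simulated arrays with no effect gave 92.0% over 100 simulations. The covariance of the changes over all genes was -0.0658 for control miRNA and -0.0584 for the mimic, against -0.0551 in the simulation and -0.0166 from the spread of the untreated arrays alone. The simulated arrays hold no real differences, so their share is not a full reference for these 784 genes. Part of the excess over 50% may come from the shared arrays, and how much was not settled. No gene passed in a comparison with a treated group, so none could pass in more than 1 comparison, and this does not bear on the question.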

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

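Against the 784 genes that differed between db/db and normal kidney, 719 of them passed again under normexp (2148 genes in all), 675 under quantile normalization (953) and 713 with the deposited ratios (758). The count was 293 with no filter on dim probes, 995 among genes well above background on all 8 arrays, 2378 with only the compared groups in the model, 1320 with a trended robust prior, 2315 with array weights, 1408 with every probe on its own, 519 at a change of at least 2-fold and 2475 at an adjusted p under 0.1. With the replicate number as a block, the replicate block, it was 474, although deviations of equally numbered arrays correlated at -0.0193 to 0.159, so the numbers do not mark pairs. Leaving out 1 array gave 20 to 3342 genes, where a lone array was assumed to vary like the other groups, and leaving out normal replicate 1 and mimic replicate 1, a setting chosen after seeing the data, gave 2379. Fewer arrays and the spread of mimic replicate 1 in the shared variance bear on these counts, and otherwise the cause was not tested. Leaving out 1 array gave 0 to 3084 genes for mimic against control miRNA and 0 to 4151 for mimic against untreated mice, where 3 genes had an adjusted p under 0.1. Of the lists that passed in camera, 0 passed with an estimated correlation in each of the 4 comparisons, and fry kept 3 for db/db against normal kidney and 0 in each of the other 3. Both methods allow for correlated members, fry also tests a list against no change and not against other genes, and the cause was not tested. For db/db against normal kidney, the estimated correlation was 0.0706 for endothelial and 0.0732 for clock genes, and these calls ended as well. Correlated members therefore need not be the reason. The simulation did not run the estimated correlation, so its power to call a list on these arrays is not known. Leaving out 1 array gave 3 to 12 lists for control miRNA against untreated mice and 8 to 24 for mimic against untreated mice. Without mimic replicate 1 the medians against control miRNA turned to -0.13 for macrophage, -0.31 for neutrophil, -0.0832 for tubular injury, -0.0173 for inflammatory cytokine and -0.0358 for interferon genes, and without mimic replicate 2 they were 1.58, 2.39, 1.19, 1.21 and 1.60. Neutrophil genes against untreated mice stood at -0.40 and 2.29 in these fits, and the difference lies in that 1 array. The opposite-sign share was 51.3% under normexp, on the other side of 50%, 47.7% under quantile normalization, 45.2% among genes well above background on all 8 arrays, 36.9% with the replicate block, and 37.8% to 46.3% when 1 array was left out. These shares are over different gene sets: the genes that passed under the setting, the 784 genes again where a control array or mimic replicate 2 was left out, and the 500 genes with the smallest p where an untreated array was left out and under 50 passed. The cause was not tested. The shift of mRNAs with seed sites in their 3′ untranslated regions was not run.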

Other observations

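Single genes of the lipid synthesis and proximal tubule lists passed in db/db kidney although the lists did not (camera adjusted p = 0.394 and 0.982). Of 31 lipid synthesis genes 1 rose and 4 fell in limma after Benjamini-Hochberg adjustment over all genes, and 1 rose and 5 fell over the list alone. Cyp51 (-2.22, adjusted p = 0.0304) and Idi1 (-1.72, 0.0205), both of the cholesterol pathway, fell together with the malic enzyme gene Me1 (-1.29, 0.0186), while Lss rose by 0.65 (0.0418). Of 18 proximal tubule genes 1 rose, the sugar transporter Slc5a10 (1.13, 0.0271), and 3 fell, namely the urate transporter Slc22a12 (-1.27, 0.0278), Keg1 (-1.10, 0.0339) and Slc17a3 (-1.41, 0.0481). Col4a3 of the glomerular basement membrane fell by 1.34 on the log2 scale (0.0287), and Pklr, a pyruvate kinase gene, rose by 0.92 (0.0325). The proton pump gene Atp6v1b1 of intercalated cells rose by 0.67 (0.0452), while Cd22 of B cells (-0.68, 0.0436) and the lysosomal gene Glb1 (-0.87, 0.0431) fell. These calls rest on 2 mice per group, and leaving out any of the 4 arrays left between 20 and 49 of the 784 calls.

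Some clock genes differed by more than 2-fold between mimic and control miRNA, though none passed. Cry1 was at 1.52 (adjusted p = 0.176), Nfil3 at 3.31 (0.183) and Nr1d1 at -2.43 (0.212), and 4 of 20 clock genes were higher and 1 lower when adjusted over the list alone.

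Immune, acute phase and tubular injury genes were high on mimic replicate 1 and not on mimic replicate 2. Of the tests below, those on albumin and on T and NK cells were chosen only after the result was seen. Relative to control miRNA, Saa1 lay at 7.70 and -0.01 on the 2 arrays, Fgb at 7.14 and 0.09, Lcn2 at 5.86 and -0.36 and Cd74 at 3.39 and 0.02, genes that were chosen after their values were seen. Liver tissue in the sample could not be judged from 7 liver markers, whose median difference was 0.187, since Alb (-2.19), Apoa2 (-0.55) and Cps1 (-0.43) were lower on mimic replicate 1 while Apoh (3.81), Apoc3 (2.45) and Ttr (1.19) were higher. T and NK cell genes differed by a median of -0.164 and B and plasma cell genes by 0.0542. These values argue against an excess of every immune cell type but do not exclude it, since the test was set after the result. Scaling was excluded as the whole cause because 2178 genes lay at least 2-fold apart after quantile normalization. Liver tissue and an acute inflammatory response in that mouse may both remain after these tests (0.187, -0.164 and 2178), and 1 mouse cannot separate the mimic from illness.

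Fat and urothelium markers were higher in the normal kidneys than in untreated db/db kidneys. The test of scaling and the split by normal array were chosen only after the result was seen. Perirenal fat and renal pelvis tissue in the normal samples would raise other markers of these tissues, and those had medians of -0.985 for 4 fat genes and -1.35 for 8 pelvis genes, although none passed on its own. Against normal replicate 1 and normal replicate 2 the pelvis medians were -1.70 and -1.06 and the fat medians -2.22 and 0.07, while the adipocyte list lay 1.54 and 0.45 above untreated db/db kidney on these arrays, so the evidence for fat rests mainly on normal replicate 1. Scaling between arrays was excluded as the whole cause, since the fat or urothelium median nearest to 0 under 3 other scalings was -0.684. Pelvis tissue taken along with the kidney may account for the lower urothelium list in db/db kidney, fat tissue (-0.985) is left open as a source common to both normal mice, and a biological loss of these cells was not tested.

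Probes with CA repeats were lower and probes with GT repeats higher on the mimic arrays. The margin of 1 standard error in the repeat length test was set after its values were seen. Other probes of the same genes had medians of 0.0164 (24 probes of 19 of the 47 CA genes) and -0.0294 (86 probes of 50 of the 107 GT genes). These values argue against a change of the genes' own transcripts for the genes they cover. The remaining genes had no other probe to test. A signal that grows with the repeat was not seen in both classes. The longest and shortest repeats stood at -1.59 and -1.17 for CA (standard error of the difference 0.245), but at 1.76 and 1.91 for GT (0.111). The classes point opposite ways, so the test cannot decide whether the signal grows with the repeat. Differences in wash, hybridization or place on the slide were not tested, since array row and column are confounded with the groups, nor was a biological explanation.

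Of 23 genes read by GA repeat probes, 9 were lower in db/db kidney (39.1%, against 784 of all 22379 genes that differed either way), with a median of -0.78. Genes within 10 Mb of Lepr were not enriched among those that differed between db/db and normal kidney (6 of 146, or 4.11%, against 3.51% elsewhere, one-sided Fisher's exact p = 0.408), so a linked haplotype was not seen as a main source. Genes whose probe holds the 7-base miR-181 site had a median of -0.0334 after the mimic, against -0.0420 for all genes, and 60.8% of 4434 other words lay at or below that value, so repression of these transcripts was not seen with both arrays. On mimic replicate 1 alone their median was -0.0339, against -0.0830 for all genes, with 80.7% of words at or below it. There 55.7% of these genes were lower, against 58.2% of all genes. On mimic replicate 2 alone their median was -0.0429, against -0.00319 for all genes, with 5.21% of words at or below it. This lay just above the 5th percentile of the words (-0.0432), the margin set in advance for both arrays together. On that array 62.1% of these genes were lower, against 50.7% of all genes. The 56 genes with the longer 8-base site had medians of -0.0085 on mimic replicate 1 and -0.0809 on mimic replicate 2. Repression was not seen on mimic replicate 1 and is left open on mimic replicate 2.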
